A study of Mus musculus with 4 samples.

How the data were processed

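Whole-exome sequencing was done on genomic DNA of c-Kit-positive leukaemia cells from the bone marrow of moribund mice whose genotype label is E2-KO, which the series title explains as an Nras-G12D allele together with loss of Ezh2. The 4 samples form 1 group on a C57BL/6 background. No control group, no matched normal tissue and no untreated sample enters the study as analysed here, so no variant is called somatic. The labels do not number the animals, so the 4 samples are called replicates 1 to 4 in the order in which they are listed, and any test across them measures only the spread between these samples, which may be technical in part.

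Exons were captured with an Agilent SureSelect mouse all-exon kit and read as pairs of 100 bases on a BGISEQ500, per the labels' protocols. Each sample has 3 deposited files. The first is a variant file made by freeBayes version 0.9.21 within SpeedSeq against UCSC mm10, 1 sample at a time, per the file headers; its quality column is a Phred-scaled score, per the file headers, and its depth, reference reads and variant reads are whole reads. The other 2 are VarScan2 tables of single-nucleotide variants (SNVs) and of indels with reference reads, variant reads and a variant frequency, per the file headers. The aligner, the treatment of duplicate reads and the VarScan2 version are not given in the sources used here. The submitters' processing notes name mm10 and GRCm38. Tested on the files, the VarScan2 tables list no site with a coverage under 8, fewer than 3 variant reads or a frequency under 20%, whereas the SpeedSeq files list sites down to a depth of 2 and to 1 variant read. At a depth of 30 or more the SpeedSeq files also list no SNV under 20%. Variants under an allele fraction of 20% are therefore outside what both callers together can show, and a fraction near this limit is biased upward. The fraction of a block near the limit was for this reason also fitted by maximum likelihood to a binomial truncated at 20%, with a profile-likelihood 95% interval.

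The variant allele fraction is variant reads divided by depth in SpeedSeq, and variant reads divided by reference plus variant reads in VarScan2. A confident SNV had a depth of at least 10, at least 3 variant reads and an allele fraction of at least 0.10 in both callers, with the same position and bases, and a SpeedSeq quality score of at least 20. SNVs at an allele fraction of 0.65 or more are called upper-range (homozygous or hemizygous in an undiluted sample) and those under it lower-range; medians of these ranges used sites with a depth of at least 30. A private SNV was confident in 1 sample and listed at its position by neither caller at any quality in the other 3. Dense bins are 2 Mb bins with at least 10 confident SNVs. Isolated private SNVs had no other private SNV of the same sample within 500 kb, a depth of at least 20 and a mean mapping quality of at least 50. This set was defined after the data were examined, because most private SNVs had another private SNV of the same sample within 500 kb. The distance to SNVs shared with other samples was not limited, so an isolated SNV can still lie inside a shared block.

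The gene table used here carries the assembly name GRCm38, the same build as mm10, and gives gene starts and ends but no exons and no sequence. Calls were therefore placed in gene bodies only, among 21887 protein-coding genes. The planned lists of protein-altering changes (missense, nonsense, splice-site and frameshift) need exons and sequence and were not computed. The planned tests of recurrence and of gene lists were run instead on isolated private SNVs inside protein-coding genes. Each sample's genes were drawn at random in proportion to gene length (10000 draws, one-sided), where the plan named coding length. Gene length includes introns, so the expected counts are not those of captured exons. The 9 gene lists were fixed before the data were examined: RAS pathway, myeloid leukaemia drivers, polycomb and chromatin regulators, cohesin and CTCF, splicing factors, JAK-STAT and cytokine signalling, DNA repair, branched-chain amino acid metabolism, and a negative control list of large or repetitive families. The rule for named genes, also fixed before, takes Nras and Ezh2, every fixed-list gene with a private variant (the control list only as a count), genes hit in 2 or more samples, and up to 5 further genes per sample. Some genes of the fixed lists are not reported here. Without coding effects the further genes were ordered by allele fraction alone.

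Shares have exact (Clopper-Pearson) 95% binomial intervals; these cover counting error only, since reads are not independent molecules. Transition shares were compared by an exact sign-flip permutation test over the 4 samples and by Fisher's exact test within each sample. Allele fractions of lower-range SNVs confident in at least 2 samples were averaged as medians of 1 Mb bins with at least 5 such SNVs, and each chromosome with at least 3 bins was compared with the other chromosomes of its sample by a two-sided permutation test (100000 permutations). Adjustment was by Benjamini-Hochberg. The chromosome test was tested on simulated data with independent bins and no blocks. It found a planted shift of -0.1 in 20 of 20 runs and made a call in 0 of 20 runs without a shift. Bins of real blocks are not independent, so these runs do not give its rate of false calls here. The search for isolated SNVs found 40 of 40 planted ones, placed on a chromosome without blocks. The truncated fit was off by at most 0.005 at true fractions from 0.10 to 0.30. Alternatives varied the depth, allele fraction and quality minimums, the caller, the window, the definition of private and isolated, and the samples included. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.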

Results

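Exome variants were measured in c-Kit-positive leukaemia cells of 4 bone marrow samples, all carrying Nras-G12D and labelled as lacking Ezh2, the catalytic subunit of Polycomb repressive complex 2. Both callers together gave 34284 confident SNVs in replicate 1, 32105 in replicate 2, 30924 in replicate 3 and 21550 in replicate 4 (mean 29716 ± 5619, SD, n = 4), and 3554, 3753, 3533 and 2861 confident indels. The median depth at these SNVs was 52, 46, 55 and 55 reads. Of the SpeedSeq SNVs that passed the filter, VarScan2 also listed 93.6% in replicate 1 (exact 95% interval 93.3 to 93.8), 91.6% in replicate 2 (91.3 to 91.9), 94.9% in replicate 3 (94.7 to 95.2) and 85.2% in replicate 4 (84.8 to 85.7); in the other direction the shares were 78.2%, 81.1%, 83.0% and 79.9%. These intervals cover counting error only. Depth limits the raw files: 76.0% of the SpeedSeq SNVs of replicate 1, 67.1% of replicate 2, 44.5% of replicate 3 and 53.0% of replicate 4 had fewer than 10 reads. None of these is a confident SNV, but their positions still counted against private SNVs of the other samples. The private and isolated counts therefore depend on these shallow calls, whose share differs between samples.

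The engineered genes were examined first, since they check the labels. All 4 samples carried the same single confident change in Nras, the small GTPase of the RAS pathway, and none carried another confident SNV in that gene. The change lies at position 103058956 of chromosome 3 (mm10), where the reference base G is read as A, within the gene body from 103058285 to 103067914. A G-to-A change is the kind that turns a glycine codon into an aspartate codon; the codon itself was not read here. The variant was present in 47.8% of reads in replicate 1 (107 of 224, exact 95% interval 41.1 to 54.5), 45.4% in replicate 2 (69 of 152, 37.3 to 53.7), 31.1% in replicate 3 (65 of 209, 24.9 to 37.9) and 42.7% in replicate 4 (91 of 213, 36.0 to 49.7). The mean was 41.7% ± 7.39 (SD, n = 4). The interval of replicate 3 does not overlap that of replicate 1 and overlaps those of replicates 2 and 4. The lower fraction of replicate 3 is not particular to Nras. Its lower-range SNVs over the whole genome had a median of 0.376, against 0.446 to 0.457 in the other samples. The mean and SD of the Nras fraction include this shift.

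Ezh2, on chromosome 6 from 47530274 to 47595270, held no confident SNV in any sample. The calls listed inside it were 2 SpeedSeq calls in replicate 1, 1 in replicate 2 and none in replicate 3 or 4, at a depth of 8 at most, and 1 VarScan2 indel at 17 reads in replicate 4. A deletion of whole exons leaves no entry in lists of this kind, so the loss of Ezh2 itself was not measured. The SNVs on both sides of the gene were upper-range in all 4 samples, although no confident SNV lay between 45060279 and 49800256 in replicates 2 and 3, 45060279 and 49827510 in replicate 4, or 45060279 and 47778211 in replicate 1. From 28 to 52 Mb the median allele fraction was 1.0 in replicate 1 (296 SNVs), 1.0 in replicate 2 (286 SNVs), 0.80 in replicate 3 (339 SNVs) and 1.0 in replicate 4 (259 SNVs), where 0.80 is also the median of the upper-range SNVs of replicate 3 over the whole genome. The flanks differed between samples: from 2 to 24 Mb the medians were 0.465, 0.461, 0.785 and 0.471 in replicates 1 to 4, and from 52 to 58 Mb they were 1.0, 1.0, 0.368 and 1.0. Of these 3 ranges, the one that is upper-range in all 4 samples is the one that contains Ezh2. The ranges were drawn to follow the fractions, so this describes them and tests nothing. The trait is also not particular to Ezh2. From 38 to 40 Mb of chromosome 17, for example, the medians were 0.99, 0.97, 0.99 and 0.98 in replicates 1 to 4.

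**Figure D1:**
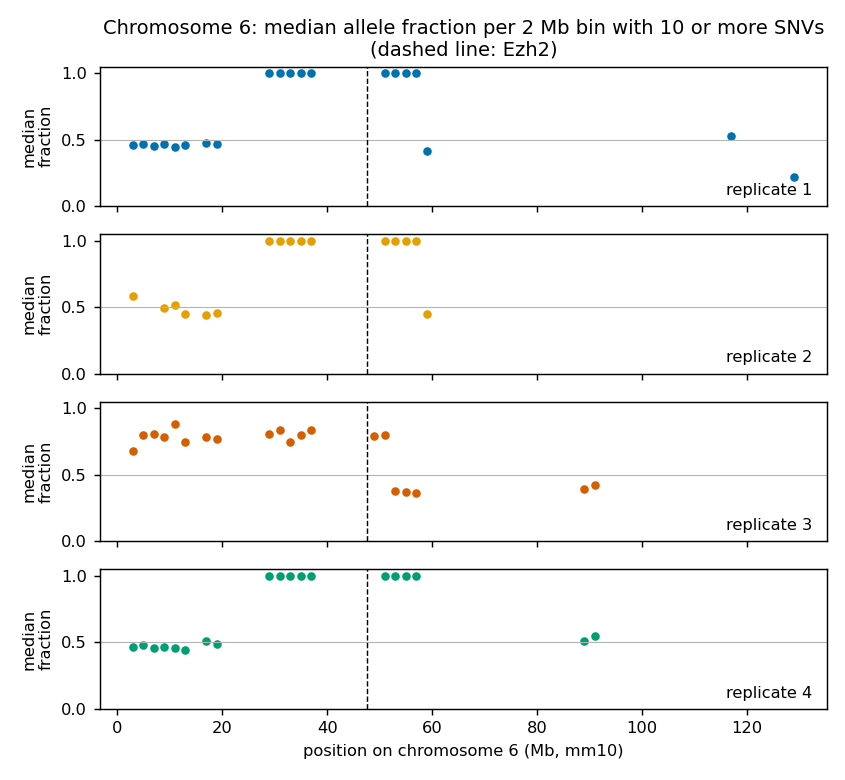
Median variant allele fraction (vertical axis, variant reads over depth) of confident SNVs in 2 Mb bins with at least 10 SNVs along chromosome 6 (horizontal axis, Mb), 1 panel per sample; the dashed line marks Ezh2 and the grey line a fraction of 0.5. Bins on both sides of Ezh2 lie at 1.0 in replicates 1, 2 and 4 and near 0.80 in replicate 3.

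The 10 Mb window centred on Ezh2 held 101, 88, 113 and 94 SNVs in replicates 1 to 4, more than 75.6%, 78.5%, 80% and 81.5% of the genome's 275 windows. The same window around Nras held 21, 12, 15 and 8 SNVs, more than 57.8%, 53.5%, 57.1% and 53.1% of windows, beside a median of 11, 9, 8 and 6 per window. Windows of 5 Mb lowered the mean percentile of Nras from 55.4 to 34.0, a move of over 1.5 times, and that of Ezh2 from 78.9 to 63.1; the nearest confident SNV below Ezh2 lies 2.47 Mb away in each sample.

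Most variants lay in dense bins rather than as scattered changes. Of 51984 confident SNV sites, 9607 (18.5%) were found in all 4 samples, 12550 in 3, 12958 in 2 and 16869 in 1. Dense 2 Mb bins made up 21.5%, 20.1%, 20.6% and 16.9% of the genome in replicates 1 to 4 and held 97.6%, 97.6%, 97.5% and 96.2% of the SNVs. Of these bins, 149 were dense in all 4 samples and 70 in a single one. Replicates 1 and 2 were the most alike, sharing 57% of the sites found in either, while the other 5 pairs shared 39.2% to 41.7%.

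The blocks showed which chromosome segments set the samples apart. On chromosome 9 between 20 and 120 Mb, replicate 3 carried 5940 SNVs at a median fraction of 0.384, 3907 of them private, whereas replicate 4 carried 51. On chromosome 1 between 168158792 and 176972424, replicates 1 and 2 carried 2262 and 2392 SNVs at medians of 0.480 and 0.460, and replicates 3 and 4 carried 10 and 7. On chromosome 13 between 20 and 40 Mb replicate 2 had no confident SNV, whereas replicates 1, 3 and 4 had 556, 575 and 584. On chromosome 2 between 140 and 160 Mb, replicates 2 and 4 had a median of 1.0 (1186 and 1232 SNVs), replicate 1 of 0.468 (1373 SNVs) and replicate 3 of 0.375 (1341 SNVs).

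**Figure D2:**
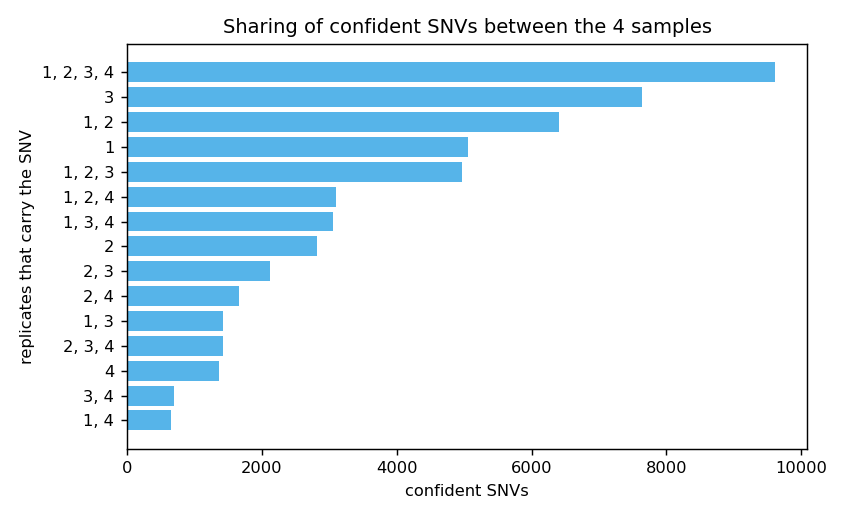
Number of confident SNVs (horizontal axis) for each combination of samples that carry them (vertical axis, replicate numbers). The set shared by all 4 samples is the highest with 9607 SNVs, followed by the 7633 confident only in replicate 3 and the 6412 confident in replicates 1 and 2.

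Private SNVs, those in which acquired changes would be sought, numbered 2686 in replicate 1, 1058 in replicate 2, 6447 in replicate 3 and 255 in replicate 4 (mean 2612 ± 2750, SD, n = 4). The mean depends on the samples and settings: it was 4865 without replicate 1, 6076 without replicate 2 and 4113 without replicate 4, since an SNV then has fewer samples to be absent from, and 4424 with VarScan2 alone, 4211 when only confident calls of the other samples counted against an SNV and 1165 without calls within 100 bp of another. Of the private SNVs, 2582, 960, 6321 and 175 had another private SNV of the same sample within 500 kb. Isolated private SNVs, which had none and also met the depth and mapping quality minimums, numbered 18, 14, 54 and 15 (mean 25.3 ± 19.2, SD, n = 4), of which 17, 11, 39 and 12 had variant reads on both strands. With VarScan2 alone the counts were 93, 81, 118 and 80 (mean 93.0), so the excess of replicate 3 was smaller. In that setting, calls absent from SpeedSeq had no mapping quality and passed its minimum unchecked. The 2 sets of counts are therefore not filtered alike. The choice of isolated SNVs, and every count that rests on them, was made after the data were examined. Isolated private indels numbered 113, 132, 108 and 74 and were not read gene by gene.

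**Figure D3:**
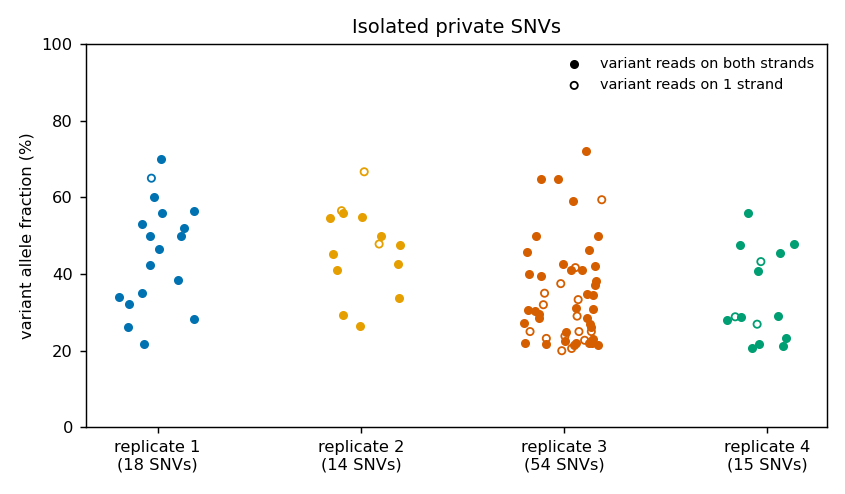
Variant allele fraction (vertical axis, percent) of each isolated private SNV by sample (horizontal axis, points spread sideways for display); filled points have variant reads on both strands and open points on 1 strand. Replicate 3 has 54 points, against 14 to 18 in the other samples.

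In the list of chromatin regulators, 5 genes had private SNVs. Kmt2a, a histone methyltransferase rearranged in leukaemia, had an isolated private SNV in replicate 3 at position 44842610 of chromosome 9, with 16 variant reads of 71 (22.5%, exact 95% interval 13.5 to 34.0). Further private SNVs of replicate 3 lay in the histone methyltransferases Kmt2c (19 SNVs, median 42.9%), Kmt2d (3 SNVs, median 83.3%) and Setd2 (2 SNVs, median 38.4%), each with other private SNVs within 500 kb, as in an inherited block. Ep300, a histone acetyltransferase, had 1 private SNV in replicate 2 at 50%, which had no neighbour but missed the depth or mapping quality required of isolated SNVs. In the cohesin list, Stag1 had 23 SNVs in replicate 3 (median 41.3%), all with neighbours.

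In the DNA repair list, Msh3, a mismatch repair gene on chromosome 13, had 1 isolated private SNV in replicate 4 (7 variant reads of 26, all on 1 strand). It also had 1 private SNV in replicate 3 (40%) that was not among the isolated ones. Msh3 lies in a dense bin that samples share: from 92 to 94 Mb, replicates 1, 3 and 4 carried 142, 148 and 152 confident SNVs. The checkpoint kinase Atr had 1 private SNV in replicate 3 (42.4%) with neighbours. No gene of the RAS pathway, myeloid driver, splicing or branched-chain amino acid list had a private confident SNV in any sample, so none of Nf1, Ptpn11, Flt3, Dnmt3a, Tet2, Runx1 or Trp53 did. Isolated hits did not exceed what gene length gives by chance in the permutation test: 1 against 0.153 expected for chromatin regulators (p = 0.143, adjusted p = 0.429 over 9 lists) and 1 against 0.0718 for DNA repair (p = 0.0696, adjusted p = 0.313). The negative control list of large and repetitive families had 5 hits against 0.661 expected (permutation p = 0.0004, adjusted p = 0.0036). The cause of this difference was not tested. All these expected counts follow gene length with introns, although exons were captured. They can be too low for genes with little intron and too high for genes with long introns. None of the list tests therefore decides whether hits are in excess.

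No protein-coding gene had isolated private SNVs in 2 or more samples (0, against 0.647 expected, one-sided permutation p = 1.0); SpeedSeq alone gave 1 such gene and VarScan2 alone 9. Leaving out genes of the fixed lists and SNVs outside protein-coding genes, the 5 isolated SNVs with the highest fractions per sample were the following. In replicate 1 the SNVs were in Palmd (70.0%, 42 of 60 reads), Tbc1d22a (65.0%, on 1 strand), Rab3a, a GTPase of vesicle release (60%), the overlapping genes Fam83g and Slc5a10 (56.5%) and Pdzk1 (55.9%, 57 of 102 reads). In replicate 2 the SNVs were in Lrba (66.7%, on 1 strand), Serpina1a, an alpha-1-antitrypsin gene with close copies (55.9%), Disc1 (55%), Trip4 (54.5%) and Papln (50%).

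In replicate 3 the SNVs were in Thoc2, a subunit of the messenger RNA export complex THO (72%, 95 of 132 reads, exact 95% interval 63.5 to 79.4), and the zinc finger gene Zfx (64.9%, 72 of 111), both on the X chromosome, and in Pcf11, a factor of 3' end cleavage (59.4%, on 1 strand), Jmjd1c, of the histone demethylase family (59.0%, 59 of 100), and Thrsp (50%, tied with Cmtm4). In replicate 4 the SNVs were in Zfp839 (47.8%), Tmem190 (45.5%), the Notch ligand Dll4 (43.2%, on 1 strand), Htra3 (40.9%) and Ezr, which encodes ezrin (28.9%, 13 of 45). Some of these isolated SNVs, such as those in Lrba and in Fam83g and Slc5a10, lie in dense bins that other samples share. Others, such as that in Palmd, do not. Whether any of these lies in an exon or changes a protein was not determined.

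Private and shared SNVs were compared by substitution type. Shared SNVs can be inherited or recurrent artefacts, and most private SNVs have private neighbours as in inherited blocks. The comparison therefore does not set acquired against inherited changes. Transitions made up 67.8% of the 9607 shared SNVs, and 64.9%, 61.2%, 74.4% and 60.4% of the private SNVs of replicates 1 to 4. The share was thus lower in private SNVs in 3 samples and higher in replicate 3, and the mean difference of -2.56 percentage points ± 6.41 (SD, n = 4) was within the spread (exact sign-flip permutation test, two-sided p = 0.5). Its direction depends on which samples define the sets, since the mean was 1.51 without replicate 1 and 2.15 without replicate 2. Without replicates 3 and 4 in turn it was -2.19 and -0.812. In each of these runs the private and shared sets were redefined among the remaining samples. An SNV otherwise found only in the left-out sample then became private. The reversal is therefore not the effect of dropping 1 sample's difference. The size of the mean difference depends on the caller, with -8.60 for VarScan2 alone and -2.81 for SpeedSeq alone. With 4 samples there are 16 sign patterns, so the smallest p is 2 of 16 and the test cannot pass 0.05. Within samples each difference passed Fisher's exact test on SNV counts (adjusted p = 0.00656, 4.35e-05, 7.43e-19 and 0.0146), although SNVs of a block are inherited together and are not independent. Among isolated private SNVs, C-to-T changes made up 5 of 18, 8 of 14, 29 of 54 and 6 of 15, against 34.5% of shared SNVs; replicate 3 passed Fisher's exact test (53.7%, adjusted p = 0.0158) and the others did not (adjusted p = 0.786, 0.184 and 0.786).

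Allele fractions were compared between samples and chromosomes, since a shift over a chromosome can mark a copy number change or loss of heterozygosity. Upper-range SNVs had a median fraction of 1.0 in replicates 1, 2 and 4 and 0.80 in replicate 3, and lower-range SNVs had medians of 0.446, 0.457, 0.376 and 0.447 in replicates 1 to 4. At the 1500 sites at 0.95 or more in replicates 1, 2 and 4 and also confident in replicate 3, replicate 3 showed 3 separate levels: 374 sites at 0.95 or more, 485 with a median of 0.804 and 641 with a median of 0.375.

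**Figure D4:**
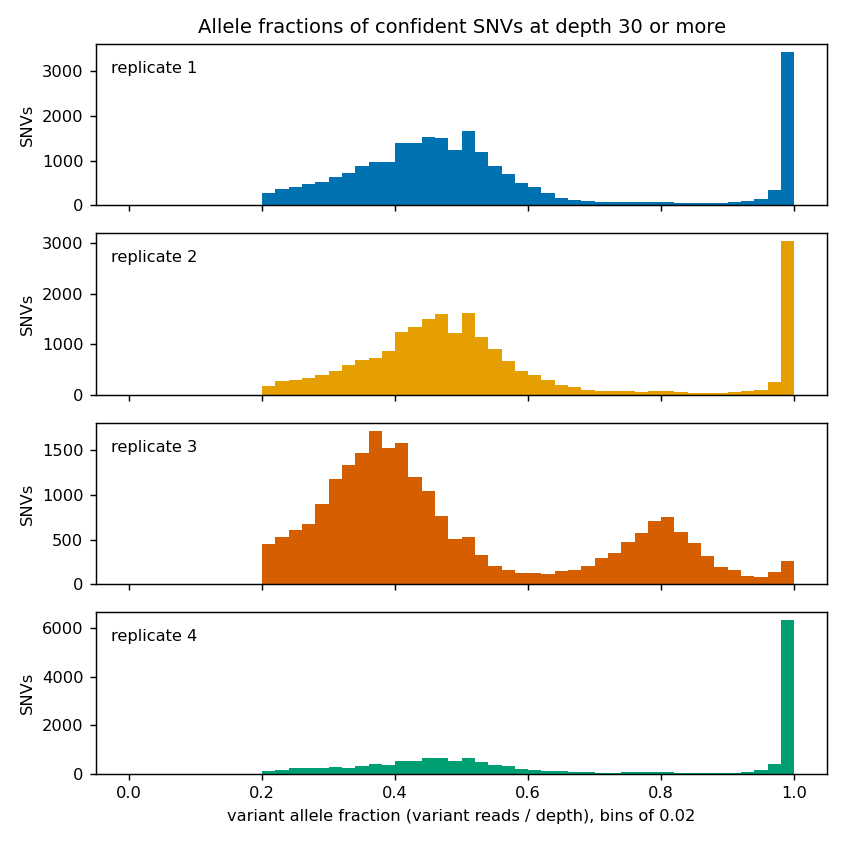
Number of confident SNVs at a depth of 30 or more (vertical axis, scaled per panel) by variant allele fraction (horizontal axis, bins of 0.02), 1 panel per sample. The upper peak stands at 1.0 in replicates 1, 2 and 4 and near 0.80 in replicate 3; no SNV lies under 0.2, the lower limit of both callers at this depth.

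Of 77 chromosome tests, 3 passed. On chromosome 19 of replicate 1 the mean bin fraction was 0.349 against 0.451 on the other chromosomes, a difference of -0.102 (permutation p = 1e-05, the smallest that 100000 permutations give; adjusted p = 0.000257). The shift came from 1 block of 1234 SNVs between 38790266 and 47988597, with a median of 0.345; the same range had medians of 0.472 in replicate 2, 0.791 in replicate 3 and 1.0 in replicate 4. At the 1075 sites that were lower-range in both replicate 1 and replicate 2, the fraction of replicate 1 was lower by a median difference of -0.123, in 10 of 10 bins of 1 Mb. Neighbouring bins of 1 block are not independent, so the permutation p is too small.

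The other 2 calls were higher fractions in replicate 3, of 0.513 against 0.400 on chromosome 11 and of 0.562 against 0.401 on chromosome 19 (adjusted permutation p = 0.000257 for both). Both chromosomes carry blocks near 0.8 in that sample (medians of 0.818 at the start of chromosome 11 and 0.791 on chromosome 19), and the upper bound of 0.65 keeps the low tail of such blocks among the lower-range SNVs.

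**Figure D5:**
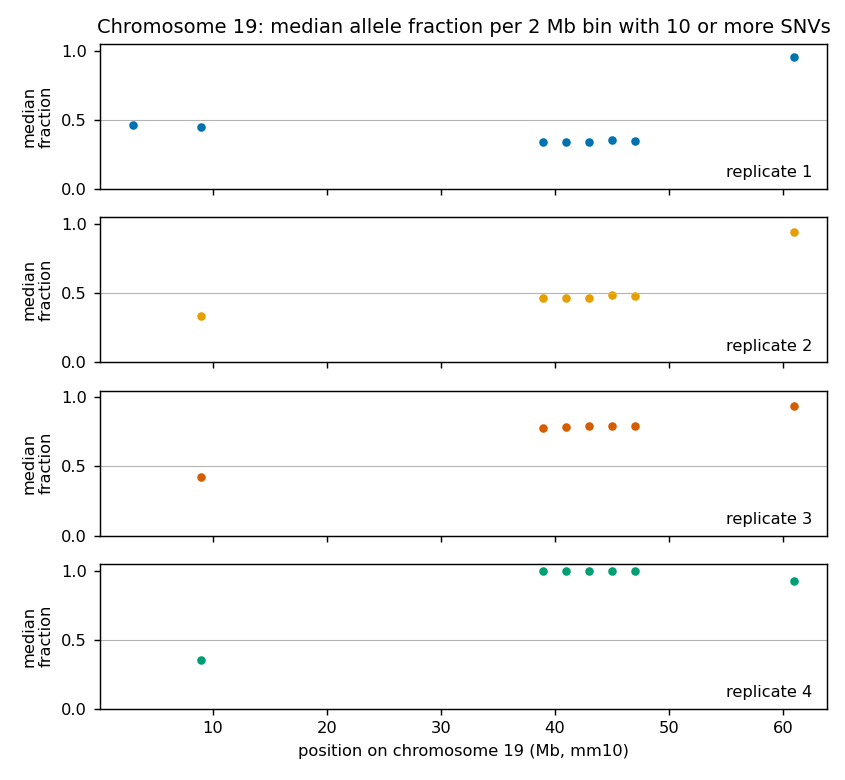
Median variant allele fraction (vertical axis) of confident SNVs in 2 Mb bins with at least 10 SNVs along chromosome 19 (horizontal axis, Mb), 1 panel per sample, with a grey line at 0.5. The block from 38 to 48 Mb has a median of 0.345 in replicate 1, 0.472 in replicate 2, 0.791 in replicate 3 and 1.0 in replicate 4.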

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

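Of the 10 tests reported in this part, 9 were chosen after the result they bear on had been seen; the exception is the share of each other library's own homozygous SNVs listed in replicate 3. The 12 per-sample quantities examined gave 3 with 1 sample far from the other 3. For normally distributed values chance gives about 1 in 20 such results. That rate does not hold for the upper-range median. It stood at its ceiling of 1.0 in 3 samples, so any lower value in the remaining sample would be flagged. The 12 quantities are also not independent of each other. The group holds no second biological condition, so no biological explanation from the design was tested.

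The median allele fraction of replicate 3 stood apart for upper-range SNVs (0.80, against 1.0 in each other sample) and for lower-range SNVs (0.376, against 0.446 to 0.457). Cells of the same animal without the leukaemia would leave its inherited homozygous SNVs near 1.0, which the median of 0.80 excludes as the whole cause. For DNA from one of the other 3 libraries, the criterion set in advance (30% or more of a library's own homozygous SNVs listed in replicate 3) was met by all 3 libraries, with 68.3% at the highest and 63.8% at the lowest; inherited sharing gives this too, so it singles out no source, whereas under 10% of the SNVs were listed in replicate 3 in 11 of 62, 7 of 46 and 12 of 86 homozygous dense bins of replicates 1, 2 and 4, against 7.1, 3.5 and 6.0 expected from the callers' limit at a share of 0.164 (at most 0.042 at 0.20), and the emptiest bin of each library argues against all 3 (binomial p at most 2.5e-09 at 0.164, Bonferroni-corrected over the library's bins, with SNVs taken as independent). DNA of an animal outside these 4 samples stays open. A block seen in replicate 3 alone on chromosome 1 (551 private SNVs from 106739225 to 149840835) had a median fraction of 0.244. The callers' limit of 0.20 biases this median upward. With that limit allowed for, the fitted fraction was 0.213 (95% interval 0.207 to 0.219). At the 77 sites with 100 or more reads it was 0.189 (0.177 to 0.201). These intervals do not overlap, and both fits take SNVs as independent, so the intervals are too narrow. Beside these fractions, a share of 0.20 was missing from the upper-range SNVs and of 0.164 from the lower-range ones. The block spans Ptprc, which encodes CD45 (13 SNVs); whether the DNA came from a congenic animal was not tested, and the labels describe no transplant.

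On chromosome 19 of replicate 1 the block from 38 to 48 Mb had a lower fraction than elsewhere in that sample. A gain of the reference chromosome large enough to give this fraction would raise the log2 depth by 0.45 and a loss of the variant chromosome would change it by -0.30, whereas the median log2 depth of the 10 bins was 0.032 (range -0.07 to 0.11), which argues against either: single bins elsewhere in the sample spread widely (SD 0.33), but the medians of 11 runs of 10 such bins on other chromosomes had an SD of 0.033 and ran from -0.08 to 0.03. Mapping bias at these sites is argued against by replicate 2, which is higher at the same sites (median difference of replicate 1 minus replicate 2 -0.123), and DNA of another animal by the upper-range median of replicate 1, which was 1.0. A copy-neutral imbalance in part of the cells (mitotic recombination, for example) may remain as a hypothesis and was not tested on other data.

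Isolated private SNVs were more numerous in replicate 3 (54, against 14 to 18). They were less so with VarScan2 alone (118, against 80 to 93), where the mapping quality minimum did not reach every call. Deeper sequencing is argued against, since the median depth of replicate 3 was 1.0 times that of the deepest other sample, replicate 4. Short inherited segments cannot be told apart from other sources: the share of C-to-T changes was above that of shared SNVs (53.7% against 34.5%, Fisher's exact p = 0.00395), which goes against SNVs of the shared kind from either animal, but it was 57.1% in replicate 2, which has no excess. SNVs brought in by a second animal stay open, since the excess lies at low fractions: 10 SNVs of replicate 3 had an exact interval above 0.30, against 2 to 11 in the other samples, whereas the intervals of 33, against 2 to 10, include 0.213. Many of these intervals are wide and also include 0.376, the lower-range median of replicate 3. The count therefore does not tell such SNVs from the sample's own lower-range ones. Isolated private indels showed no excess in replicate 3 (108, against 113, 132 and 74 in replicates 1, 2 and 4). Changes acquired by part of the cells stay open too, which calls without matched normal tissue do not separate.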

How the results depend on the processing

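Of 83 recomputed values, 67 stayed within the limits set for their result, 14 moved and 2 reversed. These limits did not hold the size of the transition difference. It went from -2.56 to -8.60 percentage points with VarScan2 alone and to -0.812 without replicate 4, and both count among the 67. The alternatives with variant reads on both strands, with other isolation distances, all those for isolated SNVs, both for the chromosome 19 shift (a depth minimum of 20 and VarScan2 reads), and those leaving samples out of the SNV calls, caller agreement and Nras fraction were chosen after the data were examined. An allele fraction minimum of 0.05 moved no count, as its limit lies below that of the VarScan2 tables. With VarScan2 alone, private SNVs rose from a mean of 2612 to 4424 per sample and isolated ones from 25.3 to 93.0. In that setting no quality score minimum applied, and calls absent from SpeedSeq passed the mapping quality minimum unchecked. How much of the rise this gives was not tested. Genes with isolated private SNVs in 2 or more samples went from 0 to 1 with SpeedSeq alone and to 9 with VarScan2 alone, and isolated hits in the fixed lists other than the control list from 2 to 3 and to 0. Defining private against the confident calls of the other samples alone gave 4211, and leaving out calls within 100 bp of another gave 1165, both by construction, as did an isolation distance of 100 kb (38 isolated SNVs). Windows of 5 Mb gave mean percentiles of 34.0 for Nras and 63.1 for Ezh2. Leaving out 1 sample in turn gave 11027 to 14579 SNVs shared by all remaining samples (highest without replicate 4, which has the fewest SNVs). Private SNVs then numbered 2215 to 6076, with fewer samples to be absent from. The mean transition difference ran from -2.19 to 2.15 percentage points. That difference turned from -2.56 to 1.51 without replicate 1 and to 2.15 without replicate 2. In all these runs the private and shared sets were redefined among the remaining samples. The Nras fraction, the caller agreement, the number of SNV calls and the chromosome 19 shift of replicate 1 stayed within the limits set for them in every alternative run for each. No paired analysis was possible because there is 1 group. The alternatives listed for protein-altering variants (per sample, by gene and by list) were not run. Depth limits what can be seen: fractions under 20% are outside the VarScan2 tables, and the median depth of 46 to 55 reads leaves wide intervals on the fraction of a single SNV.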

Other observations

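Mitochondrial DNA gave 1 confident SNV. Replicate 2 carried a C-to-T change at position 11222, in the complex I gene ND4, in 2064 of 7146 SpeedSeq reads (28.9%, exact 95% interval 27.8 to 29.9) and 28.8% of VarScan2 reads. In replicate 3, VarScan2 alone listed a T-to-C change at position 7955, where ATP8 and ATP6 overlap, in 1472 of 4890 reads (30.1%, 28.8 to 31.4). Replicate 1 had an inserted base at position 5171 in 26.3% of 414 SpeedSeq reads, and replicate 4 had no mitochondrial call in either caller. The number of nuclear copies read along with these sites was not measured.

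Dense bins differed in zygosity between the samples. Replicate 4 had 96 dense bins with a median fraction of 0.9 or more and 121 under 0.65, whereas replicate 1 had 69 and 207 and replicate 2 had 58 and 200. Replicate 3 had 10 and 206, with 57 between these limits; its upper-range SNVs have a median of 0.80, so its count at 0.9 or more is not comparable with the others. Replicate 4 also had the fewest confident SNVs and 3 dense bins of its own, against 22, 5 and 40 in replicates 1, 2 and 3.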
